A study of Homo sapiens with 30 samples.

How the data were processed

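RNA sequencing was done on Jurkat E6-1 cells, a human T cell leukaemia line, either unedited (WT) or lacking isoform 1 of SLAMF6 (KO), before and during activation with the phorbol ester PMA and the calcium ionophore ionomycin. The title of the series speaks of isoform 3 being overexpressed, while its design names a knockout of isoform 1, and the design was followed. The labels give time points 0, 6, 12, 24 and 36 without a unit. Hours were taken as the unit because the treatment protocol, written for a cytokine assay, gives its duration in hours. Each of the 10 groups of genotype and time holds 3 libraries, 30 in all. The labels do not say whether the libraries of a group come from separate cultures. The cells were lysed in TCL buffer, and RNA was cleaned up on SPRI beads before Illumina library preparation.

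The values are expected counts per gene symbol that the authors deposited, 1 file per library, for 54300 symbols in hg19-era nomenclature. Of these symbols, 195 held a value that was not whole in some library, 0.177% of all values, and these values were rounded. The submitters' processing notes name cutadapt, STAR and DESeq2 and the builds GRCh37 and hg19, without versions. The program that counted reads and its annotation are not given in the sources used here. A table of the whole series holds the same values and was not used. Positions of genes are those of GENCODE 29 on GRCh38, matched by symbol, and are not the authors' build.

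Total counts ran from 5.64 to 28.2 M per library with a median of 20.5 M. A floor of 3 counts over a group's libraries was used where a gene had no count in that group. With 1 to 3 counts in a group, levels are given without a fold, and no average over times is given for a named gene with 3 or fewer counts in a group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

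Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr at a minimum count of 10, which left 21554 symbols. Libraries were scaled with TMM. The quasi-likelihood F test was run in 1 fit of all 30 libraries with a mean for each of the 10 groups. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were each later time against 0 h within WT and within KO, KO against WT at each of the 5 times, and the average of the 5 genotype differences. The difference between genotypes in the change from 0 h was tested at each later time and jointly over the 4 later times. Levels are TMM-scaled counts per M (CPM), given as mean ± SD over the 3 libraries of a group. Log2 fold changes are those of the fit.

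Gene lists, comparisons, the rule for named genes and the first set of alternatives were chosen before the data were examined. The 28 lists cover the SLAM family, immediate early and activation transcription factors, T cell cytokines and chemokines, activation surface receptors, inhibitory receptors, T helper transcription factors, cytotoxic granule genes, NF-kB, and MAPK and calcium feedback. Others cover the T cell receptor complex, recombination and thymocyte genes, G2/M phase, S phase, glycolysis, oxidative phosphorylation and cholesterol biosynthesis. Interferon-stimulated genes, antigen presentation, and the unfolded protein and amino acid stress response have lists too. The rest cover apoptosis and arrest, migration, heat shock proteins, ribosomal proteins, mitochondrially encoded transcripts, and markers of monocytes, B cells, adherent lines and erythroid cells. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera p-values were adjusted within 4 families: WT, KO, genotype with its average, and the differences between genotypes in the change from 0 h. Camera was repeated with the correlation estimated from the data. The erythroid list kept 1 tested member and could not be tested, so 27 lists were tested in 18 comparisons.

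Named genes were SLAMF6, IL2, IFNG, TBX21 and CD69 in every comparison, and genes chosen by rule among those called. The rule asked for a mean of at least 10 CPM in a compared group and no overlap between the libraries of the groups, and excluded clone names. For activation in WT it took the 3 largest rises and 3 largest falls at each time. For genotype it took the 2 largest differences in each direction at each time, and the 10 largest in each direction in the average among genes called the same way at 4 or more times. For the differences in time course it took the 10 smallest p-values of the joint test among genes of at least 10 CPM in some group. Up to 4 members with the smallest p were taken from each list. Some genes that the rule names are not reported here.

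Numbers in the titles are shared by WT and KO libraries at 0, 6, 12 and 24 h. A pairing needed a correlation above 0.1 in all 12 such pairs, and 9 of 12 reached it, with values from -0.167 to 0.549, so the libraries were not treated as pairs. In 9 pairs each library also correlated best with the library of its own number. A replicate effect shared by the genotypes is therefore not excluded, and a replicate block was fitted as an alternative. At 0 to 24 h the titles carry the letter A in WT and B in KO. A difference tied to the letter cannot be told from genotype there. The 36 h titles carry C in both genotypes and share no numbers. Changes from 0 h to 36 h therefore cross letters, whose meaning is not known. Correlations of fold changes across genes carry no p-value, since genes are not independent replicates.

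The alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors in place of TMM, no filter on low counts, a fit of the 6 compared libraries alone, a replicate block from the shared numbers, the average and joint tests without the 36 h libraries, camera with an estimated correlation, and leaving out each library in turn. Added after seeing the data were fits without the outlying KO libraries of 6 h and 12 h, without both replicate 3 libraries of 24 h, and without the 12 h libraries.

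The pipeline was tested on simulated data with 50 planted genes per fold and 20681 genes tested. Planted genes averaged above 1 CPM, and counts were drawn independently for each gene and library. The shares below therefore do not cover weaker genes. Neither the shares nor the false calls cover library effects shared between genes. For KO against WT at 0 h it recovered 32%, 76%, 88% and 96% of genes planted at 1.5-, 2-, 4- and 8-fold, with 5 false calls. The shares at 6 h were 32%, 70%, 84% and 98% with 8 false calls, and at 12 h 42%, 74%, 84% and 100% with 9. At 24 h they were 38%, 66%, 84% and 100% with 6 false calls, and at 36 h 38%, 72%, 88% and 100% with 16. In the average they were 84%, 94%, 100% and 100% with 14. For the difference in the change from 0 h to 36 h they were 16%, 46%, 86% and 94% with 6 false calls, and for the joint test 16%, 50%, 88% and 98% with 11.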

Results

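Transcript levels were measured in Jurkat T cells, WT or KO for SLAMF6 isoform 1, at 0, 6, 12, 24 and 36 h of activation with PMA and ionomycin, which mimic T cell receptor signalling by activating protein kinase C and raising calcium. SLAMF6 encodes a receptor of the SLAM family on lymphocytes. Each of the 10 groups held 3 libraries. At 0 h the WT libraries held 26.5, 7.59 and 28.2 M counts and the KO libraries 24.2, 5.64 and 28.0 M. At 6 h they held 21.97, 21.0 and 21.8 M in WT and 22.2, 24.1 and 21.1 M in KO. At 12 h they held 13.8, 19.5 and 15.7 M in WT and 20.8, 21.1 and 19.3 M in KO. At 24 h they held 16.2, 12.4 and 16.7 M in WT and 17.8, 16.3 and 20.4 M in KO. At 36 h they held 21.8, 8.54 and 20.7 M in WT and 16.2, 18.8 and 26.3 M in KO. Levels below are TMM-scaled counts per M (CPM), mean ± SD of 3 libraries. Largest rises and falls are given among called genes of at least 10 CPM in a compared group whose libraries do not overlap. P-values measure only the spread between these libraries, because no label says that they come from separate cultures.

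SLAMF6 transcript rose during activation in both genotypes and was not called lower in KO at any time. In WT it went from 21.2 ± 3.4 CPM at 0 h to 38.8 ± 2.37, 51.3 ± 1.92, 78.8 ± 16.6 and 105 ± 5.9 CPM at 6, 12, 24 and 36 h. In KO it went from 19.3 ± 1.47 to 42.3 ± 4.91, 52.5 ± 6.05, 123 ± 20.7 and 139 ± 12.8 CPM. KO exceeded WT at 24 h, with a log2 difference of 0.64 (SE 0.128, adjusted p = 0.000608), and at 36 h, with 0.41 (SE 0.127, adjusted p = 0.0269). The values at 0, 6 and 12 h were -0.13, 0.12 and 0.03 (adjusted p = 0.682, 0.661 and 0.909). The 36 h call was lost without WT replicate 1 or 2 or KO replicate 1 or 3 (adjusted p = 0.0989, 0.0928, 0.0885 and 0.125). Counts per gene sum over isoforms, so they neither show nor exclude the loss of isoform 1. The title of the series speaks of isoform 3 being overexpressed and its design of a knockout of isoform 1. The design was followed here, and no value below settles which is right. SLAMF6 lies on the minus strand of chromosome 1 at 160485030 to 160523262 (GENCODE 29 on GRCh38).

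**Figure D1:**
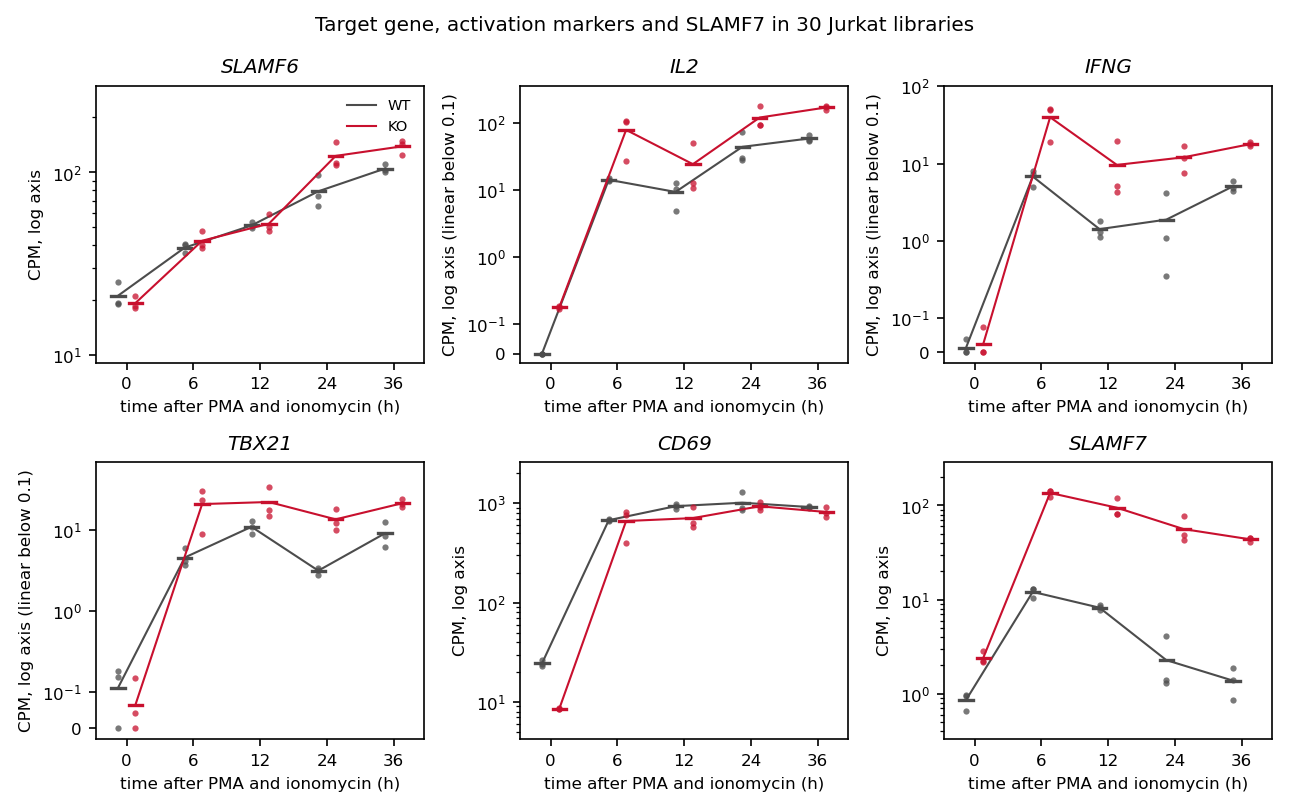
Levels of SLAMF6, IL2, IFNG, TBX21, CD69 and SLAMF7 in CPM (log scale, linear below 0.1) against time in hours (steps not to scale), with points for libraries and short bars and lines for means of the 3 libraries in WT and KO. IL2 and IFNG were near 0 before activation in both genotypes, and SLAMF7 reached 136 CPM in KO against 12.1 CPM in WT at 6 h.

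The first question was which transcripts activation changed in WT cells. At 6 h the cytokine IL2 went from 0 counts to 14.3 ± 0.772 CPM, at least 287-fold higher, and the chemokine IL8 from 0 to 12.0 ± 0.499 CPM, at least 242-fold higher. The chemokine CCL4 was at 36.8 ± 5.42 CPM against 0.0389 CPM (3 counts) at 0 h. The largest falls were in RAG1 and RAG2, the recombinase that assembles antigen receptor genes, with log2 changes of -4.83 and -4.35, and in the non-coding RNA LINC00977, with -3.64. IFNG, the effector cytokine interferon gamma, was at 6.8 ± 1.69 CPM against 0.013 CPM (1 count), and the early activation receptor CD69 rose from 24.4 ± 1.84 to 675 ± 17.8 CPM. TBX21, the transcription factor T-bet, rose from 0.113 to 4.56 CPM. The plot of marker levels shows these genes by library.

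By list at 6 h in WT, 20 of 25 cytokine genes rose and 1 fell (20 and 1 adjusted over the list alone; median log2 4.01, camera adjusted p = 1.17e-15). Of 22 immediate early and activation transcription factors 16 rose and 1 fell (16 and 3 adjusted over the list alone), of 19 NF-kB genes 15 and 1, of 22 MAPK and calcium feedback genes 15 and 1, and of 18 activation receptors 13 and 2. The unfolded protein response raises chaperones of the endoplasmic reticulum. Its list, called the unfolded protein list below, also holds amino acid stress genes such as ASNS and PHGDH. Of its 25 genes 17 rose and 2 fell (18 and 3 adjusted over the list alone, camera adjusted p = 6.75e-13). Of 18 antigen presentation genes 12 rose and 0 fell, and of 18 recombination and thymocyte genes 0 rose and 12 fell. S phase genes fell in 22 of 25 cases (adjusted p = 2.4e-20). The SLAM family rose in 9 of 14 members and fell in 3, apoptosis and arrest genes rose in 11 of 24 and fell in 1. T helper factors rose in 11 of 24 cases and fell in 3, and cytotoxic granule genes rose in 7 of 14 and fell in 3. All of these list calls held with an estimated correlation. Lists called only with the preset correlation were G2/M with 11 of 25 genes lower (adjusted p = 0.268 with an estimated correlation), interferon-stimulated genes with 12 of 31 higher and 2 lower (adjusted p = 0.196). So were heat shock proteins with 7 of 13 lower (adjusted p = 0.0651), and oxidative phosphorylation with 8 of 34 lower and 1 higher (adjusted p = 0.387). In all, 4833 of 21554 genes were called, 2548 higher and 2285 lower.

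At 12 h in WT, BCL2A1, an NF-kB target that blocks cell death, rose to 38.7 ± 8.23 CPM from 0.0762 CPM (log2 8.52, SE 0.656, adjusted p = 1.02e-09). The chemokine XCL2 was at 26.5 ± 8.12 CPM against 0.0259 CPM (2 counts) at 0 h, and CCL4 at 32.5 ± 10.3 CPM. LINC00977, RAG2 and RAG1 fell, with log2 changes of -5.69, -4.17 and -4.11. S phase genes fell in 24 of 25 cases (24 adjusted over the list alone; median log2 -1.63, adjusted p = 1.12e-30). Cholesterol biosynthesis genes fell in 15 of 24 cases with 0 higher (17 lower adjusted over the list alone; adjusted p = 2.67e-08). Interferon-stimulated genes rose in 23 of 31 cases and antigen presentation genes in 14 of 18, with 0 lower in each over all genes. Among the lists called with the preset correlation and not otherwise were G2/M with 16 of 25 genes lower and 1 higher (adjusted p = 0.129 with an estimated correlation) and glycolysis with 13 of 22 lower and 4 higher (adjusted p = 0.169). The unfolded protein list had 7 members higher and 9 lower and was not called (adjusted p = 0.0593). Of all genes 6517 were called, 3161 higher and 3356 lower, and the median log2 change of all tested genes was 0.116 (0.154 with DESeq2 size factors). The WT libraries of 12 h held counts for 35977 ± 3300 symbols, against 29868 ± 4937 at 0 h.

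At 24 h in WT, XCL2 reached 357 ± 230 CPM, IL2 44.3 ± 26.2 CPM, at least 893-fold higher than at 0 h, and CSF2, the growth factor GM-CSF, 42.0 ± 20.1 CPM, at least 846-fold higher. RAG2, LINC00977 and the growth factor gene PDGFC fell, with log2 changes of -6.05, -5.13 and -5.12. WT replicate 3 stood apart in IL2, at 74.5 CPM against 30.1 and 28.3 CPM. All 25 G2/M genes fell (25 adjusted over the list alone; median log2 -2.03, adjusted p = 2.38e-34), and 24 of 25 S phase genes fell (24 adjusted over the list alone; median log2 -1.92). Inhibitory receptors and exhaustion-associated genes rose in 9 of 13 cases with 0 lower (9 adjusted over the list alone; adjusted p = 4.23e-05). Cholesterol genes fell in 17 of 24 cases with 1 higher, and interferon-stimulated genes rose in 27 of 31 with 2 lower. Of all genes 7372 were called, 3715 higher and 3657 lower.

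At 36 h in WT, CSF2 reached 120 ± 12.9 CPM, at least 2430-fold above 0 h, IL2 59.1 ± 6.66 CPM, at least 1190-fold, and XCL2 621 ± 16.8 CPM. DNTT, the terminal transferase of immature lymphocytes, fell from 179 ± 18 to 0.661 ± 0.515 CPM. RAG2 and the myosin gene MYO7B fell, with log2 changes of -6.66 and -5.99, the latter from 1167 ± 102 to 18.4 ± 1.67 CPM. G2/M genes fell in 25 of 25 cases (25 adjusted over the list alone; median log2 -2.49, adjusted p = 1.27e-35), among them CDC20, with a log2 change of -3.20, and BUB1B, with -2.82. Cytokines rose in 18 of 25 cases and fell in 2 (20 and 2 adjusted over the list alone; median log2 5.09). HLA-B, a class I antigen presentation gene, rose from 87.6 ± 3.05 to 934 ± 48.3 CPM. Cholesterol genes fell in 17 of 24 cases and rose in 2 (17 and 2 adjusted over the list alone; adjusted p = 5.72e-06). Ribosomal protein genes fell in 22 of 45 cases and rose in 1 (adjusted p = 0.588 with an estimated correlation), and migration genes fell in 12 of 24 and rose in 4 (adjusted p = 0.0881 with an estimated correlation). Of all genes 8416 were called, 4329 higher and 4087 lower.

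The same comparisons in KO gave 5849, 5995, 7063 and 7880 called genes at 6, 12, 24 and 36 h. IL2 in KO went from 0.178 ± 0.00908 CPM (10 counts) to 79.4 ± 45.5, 24.4 ± 22.1, 122 ± 50.1 and 172 ± 10.5 CPM. IFNG went from 0.0251 CPM (2 counts) to 39.9 ± 17.9, 9.61 ± 8.54, 12.1 ± 4.8 and 17.9 ± 1.21 CPM. Cytokine genes rose in 19, 18, 18 and 19 of 25 cases and fell in 1, 1, 0 and 1 (20, 18, 19 and 19 higher adjusted over the list alone), with median log2 changes of 5.17, 3.81, 6.57 and 6.90. S phase genes fell in 23, 24, 24 and 23 of 25 cases. G2/M genes fell in 21, 19, 25 and 25 of 25 cases, and the 12 h call had an adjusted p = 0.0683 with an estimated correlation. The unfolded protein list rose at all 4 later times, with 16, 14, 14 and 16 of 25 members higher and 5, 4, 3 and 2 lower. In cholesterol biosynthesis 14, 13 and 14 of 24 genes were higher at 6, 12 and 24 h and 3, 2 and 4 lower (adjusted p = 0.119, 0.107 and 0.179 with an estimated correlation), and at 36 h 7 were higher and 5 lower (adjusted p = 0.636). Fold changes of activation in WT and in KO correlated across genes with r = 0.544, 0.599, 0.606 and 0.601, and with no filter on low counts r = 0.17, 0.21, 0.205 and 0.219. Without 1 library, where the filter kept more genes, these r ran from 0.413 to 0.543. At 6 h 1667 genes rose in both genotypes, where independent calls would give 358, and 31 were called in opposite directions.

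**Figure D2:**
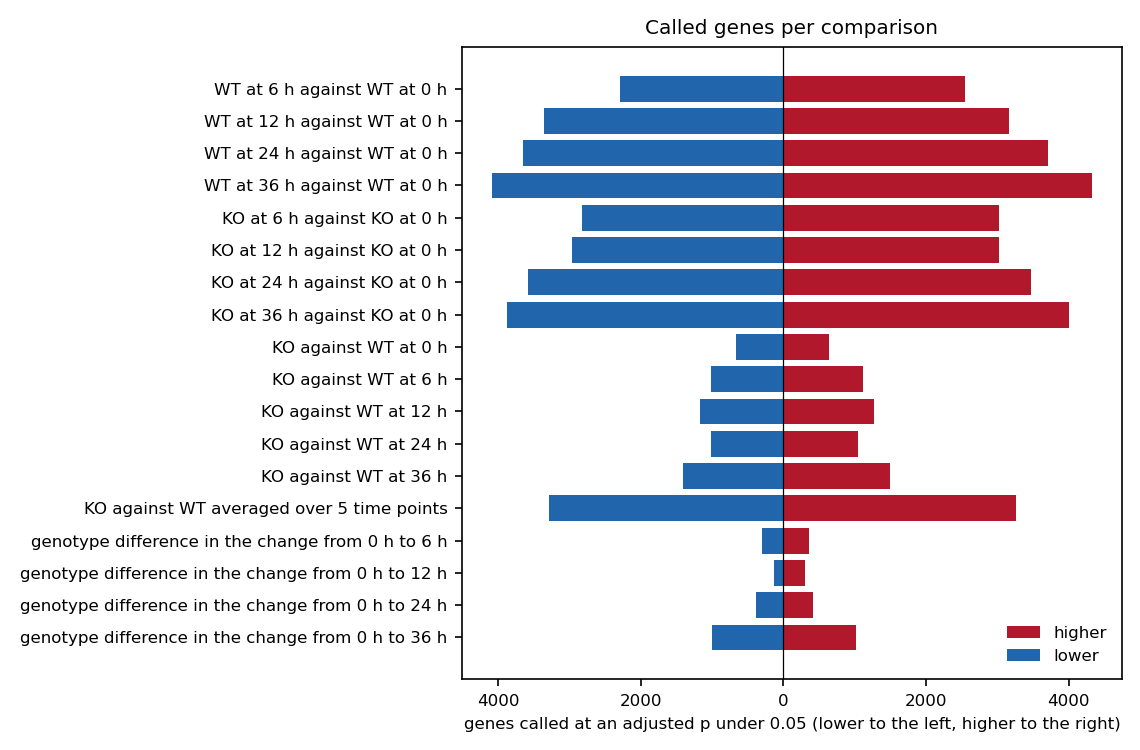
Number of genes called lower (bars to the left) and higher (bars to the right) in each of the 18 comparisons with a direction. Activation changed 4833 to 8416 genes within a genotype, and KO differed from WT in 1309 to 2906 genes at single times.

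The main question was how KO cells differed from WT cells. The sample titles do not say how many edited lines the KO libraries come from. Other differences between the WT and KO lines therefore cannot be told from the loss of isoform 1. At 0 h, TXNIP, an inhibitor of thioredoxin and of glucose uptake, was at 22.2 ± 0.408 CPM in KO and 2.92 ± 1.14 CPM in WT (log2 2.83, SE 0.313, adjusted p = 1.1e-07), and FAM110B at 17.2 ± 2.13 against 2.64 ± 0.804 CPM. RNF212 was at 0.217 ± 0.19 CPM in KO against 31.6 ± 1.26 CPM in WT (log2 -7.54, SE 0.442, adjusted p = 1.63e-14), and CD40LG, the ligand by which T cells activate B cells, at 0.235 ± 0.113 against 22.7 ± 1.99 CPM. CD69 was lower, at 8.57 ± 0.133 against 24.4 ± 1.84 CPM (log2 -1.51, SE 0.228, adjusted p = 0.000106). Cholesterol biosynthesis was lower in 14 of 24 genes and higher in 1 (18 and 1 adjusted over the list alone; median log2 -0.42, camera adjusted p = 1.71e-16), with the pathway enzyme genes IDI1 and MSMO1 at -0.95 and -1.12. In the unfolded protein list 9 of 25 genes were lower and 1 higher (9 and 3 adjusted over the list alone; adjusted p = 0.000161). HSPA5, the main chaperone of the endoplasmic reticulum, was at 676 ± 64.4 against 2247 ± 137 CPM and HERPUD1 at 57.3 ± 3.59 against 181 ± 4.52 CPM. That list was called lower and had a mean of -0.27, while its median was 0.03.

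Other lists at 0 h moved too. Activation receptors were lower in 5 of 18 cases (7 adjusted over the list alone; adjusted p = 1.4e-05) and immediate early factors in 3 of 22 with 1 higher (3 and 1 adjusted over the list alone; adjusted p = 0.00724), where EGR1 was lower by a log2 of -2.75 and JUN higher by 1.71. T helper factors were higher in 8 of 24 cases and lower in 1 (9 and 1 adjusted over the list alone; adjusted p = 7.38e-05), with STAT4 at 45.2 ± 1.05 against 11.3 ± 1.76 CPM. NF-kB genes were higher in 5 of 19 cases (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.000814), with BIRC3 at a log2 of 1.29. Among the calls that ended with an estimated correlation were glycolysis, 8 of 22 lower (adjusted p = 0.0558 with an estimated correlation), and recombination and thymocyte genes, 4 of 18 lower and 1 higher (adjusted p = 0.0507). The same held for antigen presentation, 6 of 18 higher and 1 lower (adjusted p = 0.105), interferon-stimulated genes, 5 of 31 higher and 1 lower (adjusted p = 0.396), and mitochondrially encoded transcripts, 4 of 13 higher (adjusted p = 0.269). In all 1309 genes were called, 641 higher and 668 lower, with 130 at least 2-fold higher and 344 at least 2-fold lower. Of these, 53 and 57 were genes of at least 10 CPM, and 7 and 91 were genes under 1 CPM. The count fell to 650, 760 or 696 without WT replicate 1, KO replicate 1 or KO replicate 3, and the higher share went from 49.0% to 39.3% with DESeq2 size factors.

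At 6 h, GZMB, the granule protease granzyme B, was at 2560 ± 658 CPM against 230 ± 17.5 CPM in WT (log2 3.48, SE 0.392, adjusted p = 2.74e-06). IFNG was at 39.9 ± 17.9 against 6.8 ± 1.69 CPM (log2 2.55, adjusted p = 0.0032), TBX21 at 20.8 ± 11 against 4.56 CPM (log2 2.18, adjusted p = 0.000197) and EOMES, a transcription factor of cytotoxic cells, at 53.4 ± 27.4 against 8.81 ± 0.886 CPM. The lists of cytotoxic granule genes (3 of 14 higher, 1 lower; adjusted p = 0.143) and T helper factors (7 of 24 higher, 2 lower; adjusted p = 0.134) were not called. IL2 was at 79.4 ± 45.5 against 14.3 ± 0.772 CPM (log2 2.48, SE 0.57, adjusted p = 0.00768), a call that was lost in a fit of the 6 libraries alone (adjusted p = 0.0597). KO replicate 2 stood apart, with IL2 at 26.9 CPM against 108 and 104 CPM. SLAMF7, another SLAM receptor, was at 136 ± 10.7 against 12.1 ± 1.57 CPM. By the rule for single times, ARC at 50.5 ± 0.765 against 3.94 ± 2.42 CPM and PLAU, the protease urokinase, at 149 ± 45.5 against 11.8 ± 1.42 CPM showed the largest rises. The largest falls were in RNF212, at 0.0478 CPM (3 counts) against 16.4 ± 2.44 CPM, and CPXM1 (log2 -7.47, SE 0.404, adjusted p = 3.39e-16). CD69 was not called, at 662 ± 229 against 675 ± 17.8 CPM.

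By list at 6 h, cytokine genes were higher in 10 of 25 cases and lower in 1 (15 and 1 adjusted over the list alone; median log2 2.03, adjusted p = 1.64e-08), with TNF at 32.8 ± 6.77 against 5.54 ± 1.07 CPM and LTA at 55.1 ± 3.61 against 10.9 ± 3.87 CPM. NF-kB genes were higher in 10 of 19 cases and lower in 1 (12 and 2 adjusted over the list alone), MAPK and calcium feedback genes in 4 of 22 and 1 (8 and 1), apoptosis and arrest genes in 8 of 24 and 0 (9 and 0), and antigen presentation genes in 12 of 18 and 2 (12 and 2). CDKN1A, the cell cycle inhibitor p21, was at 157 ± 31.5 against 47.0 ± 3.62 CPM. G2/M genes were lower in 18 of 25 cases (22 adjusted over the list alone; median log2 -0.50, adjusted p = 4.82e-18), with CENPF at -1.02. Unfolded protein genes were lower in 14 of 25 cases and higher in 4 (14 and 4 adjusted over the list alone; adjusted p = 3.38e-09), with HSPA5 at 2730 ± 201 against 6856 ± 145 CPM. Recombination and thymocyte genes were lower in 6 of 18 cases with 0 higher (7 and 2 adjusted over the list alone; adjusted p = 0.00207). Among the calls that ended with an estimated correlation were activation receptors, 5 of 18 higher and 1 lower (adjusted p = 0.173 with an estimated correlation), the T cell receptor list, 7 of 23 lower and 2 higher (adjusted p = 0.138), and interferon-stimulated genes, 8 of 31 higher (adjusted p = 0.32). In all 2141 genes were called, 1121 higher and 1020 lower, with 321 at least 2-fold higher and 381 lower. Among genes of at least 10 CPM these were 156 and 100. The count fell to 1412, 1363 or 1376 without WT replicate 2, WT replicate 3 or KO replicate 1, and the higher share went from 52.4% to 49.2% with DESeq2 size factors.

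At 12 h, SLAMF7 was at 94.7 ± 23.1 CPM in KO against 8.21 ± 0.497 CPM in WT (log2 3.53, SE 0.247, adjusted p = 7.9e-11) and PLAU at 51.2 ± 24.7 against 4.53 ± 0.803 CPM. RNF212 was at 0.0321 CPM (2 counts) against 10.6 ± 0.944 CPM, and CPXM1 at a log2 of -6.58. Cholesterol genes were now higher in 15 of 24 cases and lower in 1 (16 and 1 adjusted over the list alone; median log2 0.44, adjusted p = 2.12e-10), with MVK at 59.5 ± 4.8 against 25.4 ± 5.17 CPM. Unfolded protein genes were higher in 9 of 25 cases with 0 lower (10 adjusted over the list alone; adjusted p = 2.62e-05), among them DDIT3, the stress factor CHOP, at 77.8 ± 17.3 against 32.2 ± 1.75 CPM. Antigen presentation genes were higher in 13 of 18 cases and lower in 1 (13 and 2 adjusted over the list alone; adjusted p = 5.89e-13), with TAP1 at 1314 ± 75.2 against 664 ± 112 CPM. NF-kB genes were higher in 10 of 19 with 0 lower (13 adjusted over the list alone), with BIRC3 at 415 ± 45.8 against 123 ± 7.97 CPM, apoptosis and arrest genes in 10 of 24 with 1 lower (11 and 2), and MAPK and calcium feedback genes in 9 of 22 with 1 lower (10 and 3). Inhibitory receptors and exhaustion-associated genes were lower in 3 of 13 cases (4 adjusted over the list alone; adjusted p = 0.0019), among them TOX2 at a log2 of -3.79. In other members KO replicate 1 was level with WT, as in PDCD1 at 64.0 CPM against 56.1 to 75.9 CPM in WT and 11.2 and 8.74 CPM in KO replicates 2 and 3. Thymocyte genes were lower in 5 of 18 cases at 12 h (8 lower and 1 higher adjusted over the list alone; adjusted p = 0.000108). LEF1, a transcription factor of immature T cells, was at 225 ± 32 against 573 ± 35.6 CPM.

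IFNG at 12 h was at 9.61 ± 8.54 CPM in KO against 1.42 ± 0.369 CPM in WT (log2 2.74, adjusted p = 0.00701), a call lost without KO replicate 1 (adjusted p = 0.0676) or with the 6 libraries alone (adjusted p = 0.0653). KO replicate 1 stood apart with IL2 at 49.9 CPM against 10.7 and 12.6 CPM. IL2 (log2 1.39) and TBX21 (log2 1.02) did not pass (adjusted p = 0.142 and 0.0591). TBX21 passed with the replicate block (0.0233) and without KO replicate 3 (0.0338). CD69 did not pass (adjusted p = 0.183) but did without KO replicate 1 (0.0394). Cytokine genes were higher in 5 of 25 cases (adjusted p = 0.294 with an estimated correlation), S phase genes lower in 8 of 25 and higher in 2 (adjusted p = 0.332), heat shock proteins lower in 5 of 13 and higher in 1 (adjusted p = 0.231), and G2/M genes lower in 2 of 25 (adjusted p = 0.595). In all 2452 genes were called, 1278 higher and 1174 lower, and the higher share went from 52.1% to 38.8% with DESeq2 size factors. At least 2-fold, 298 were higher and 868 lower. Among genes of at least 10 CPM these were 170 and 95, and among genes under 1 CPM 7 and 227. WT libraries of this time held counts for 35977 ± 3300 symbols and KO libraries for 30123 ± 422. The count of calls fell to 1353 or 1588 without WT replicate 2 or KO replicate 2.

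At 24 h, SLAMF7 was at 56.2 ± 18.6 CPM in KO against 2.28 ± 1.61 CPM in WT (log2 4.61, SE 0.285, adjusted p = 7.67e-12) and XIRP1, an actin-binding protein gene, at 89.6 ± 35.5 against 4.0 ± 0.572 CPM. RNF212 and CPXM1 were lower by log2 values of -6.12 and -5.26. Cholesterol genes were higher in 16 of 24 cases and lower in 1 (19 and 1 adjusted over the list alone; median log2 0.42, adjusted p = 1.13e-14), with MSMO1 at 401 ± 18.8 against 211 ± 51.4 CPM and SREBF2, the transcription factor of the pathway, at 1.09. G2/M genes were lower in 17 of 25 cases (17 adjusted over the list alone; adjusted p = 7.26e-15), with CDK1 at 74.5 ± 7.84 against 132 ± 11.7 CPM, and S phase genes in 13 of 25 (16 lower and 1 higher adjusted over the list alone; adjusted p = 6.28e-11). Cytotoxic granule genes were higher in 6 of 14 cases and lower in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.000109), with GZMB at 70.5 ± 31.2 against 17.7 ± 11.1 CPM. Cytokines were higher in 8 of 25 cases and lower in 2 (12 and 2 adjusted over the list alone; adjusted p = 7.96e-07), with TNFSF8 at a log2 of 2.01 and IL13, a type 2 cytokine, at -2.45. LEF1 was at 484 ± 81.6 against 1424 ± 318 CPM.

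Also at 24 h, antigen presentation genes were higher in 10 of 18 cases and lower in 1, unfolded protein genes in 8 of 25 and 0, NF-kB genes in 5 of 19 and 0, and MAPK and calcium feedback genes in 7 of 22 and 0. The counts higher and lower were 13 and 1, 13 and 0, 9 and 0, and 7 and 1 adjusted over the list alone. IFNG (log2 2.67, adjusted p = 0.00729) and TBX21 (log2 2.10, adjusted p = 0.000761) were higher, while IL2 at 122 ± 50.1 against 44.3 ± 26.2 CPM did not pass (log2 1.45, adjusted p = 0.108). IL2 passed with the replicate block (0.0261) and without WT replicate 3 (0.0428). Among the calls that ended with an estimated correlation were interferon-stimulated genes, 8 of 31 higher and 1 lower (adjusted p = 0.259 with an estimated correlation), the T cell receptor list, 8 of 23 lower and 2 higher (adjusted p = 0.32), and apoptosis and arrest genes, 6 of 24 higher and 3 lower (adjusted p = 0.0507). In all 2058 genes were called, 1048 higher and 1010 lower, with 335 at least 2-fold higher and 320 lower. Among genes of at least 10 CPM these were 159 and 97. The replicate 3 libraries of both genotypes stood above the others in IL2, at 74.5 CPM in WT and 179 CPM in KO. The count was 1354 without KO replicate 3, 1259 without both replicate 3 libraries and 986 with the 6 libraries alone, and the higher share went from 50.9% to 46.0% with DESeq2 size factors.

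At 36 h, SLAMF7 was at 43.6 ± 2.45 CPM in KO against 1.38 ± 0.5 CPM in WT (log2 4.88, SE 0.299, adjusted p = 4.56e-12), XIRP1 at 57.6 ± 8.34 against 4.22 ± 0.369 CPM, and ANXA1, the regulator of inflammation annexin A1, at 197 ± 21.1 against 28.97 ± 4.04 CPM. RNF212 (log2 -6.50) and CD40LG, at 0.755 ± 0.438 against 33.2 ± 3.24 CPM, showed the largest falls. G2/M genes were lower in 19 of 25 cases (23 adjusted over the list alone; median log2 -0.53, adjusted p = 1.71e-16), with CCNB2 at 28.5 ± 2.38 against 57.0 ± 4.38 CPM. Cytotoxic granule genes were higher in 8 of 14 cases (8 adjusted over the list alone; adjusted p = 1.2e-05), with GZMA at 363 ± 45.2 against 136 ± 22 CPM. Unfolded protein genes were higher in 11 of 25 cases (11 adjusted over the list alone; adjusted p = 2.19e-07), with DDIT3 at 61.7 ± 2.95 against 22.5 ± 1.73 CPM. Apoptosis and arrest genes were higher in 7 of 24 cases and lower in 1, with CDKN1A at 29.2 ± 3.21 against 4.8 ± 1.57 CPM, NF-kB genes in 5 of 19 and 1, and MAPK and calcium feedback genes in 8 of 22 and 2 (7 and 1, 9 and 1, and 10 and 2 adjusted over the list alone). Antigen presentation genes were higher in 8 of 18 cases and lower in 2 (12 and 3 adjusted over the list alone; adjusted p = 7.05e-06), with a median of 0.29 and a mean of -0.19.

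Also at 36 h, cytokines were higher in 10 of 25 cases and lower in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.085 with an estimated correlation), with CCL5 at 19.9 ± 1.61 against 1.53 ± 0.251 CPM and IL13 at 2.18 ± 0.55 against 20.2 ± 3.14 CPM. Ribosomal protein genes were higher in 31 of 45 cases (41 adjusted over the list alone; adjusted p = 0.167 with an estimated correlation) and mitochondrially encoded transcripts lower in 4 of 13 (adjusted p = 0.32 with an estimated correlation). Mitochondrially encoded reads were 4.9% ± 0.598 of counts in KO and 8.84% ± 0.66 in WT. IL2 was at 172 ± 10.5 against 59.1 ± 6.66 CPM and did not pass (log2 1.54, adjusted p = 0.0664), although the 6 libraries alone gave an adjusted p of 5.53e-12 and DESeq2 one of 0.0375. IFNG (log2 1.84, adjusted p = 0.0299) and TBX21 (log2 1.23, adjusted p = 0.0199) passed. The IFNG call was lost without any 1 of the 6 libraries of this time (adjusted p from 0.057 to 0.114), and the TBX21 call without WT replicate 1 or 2 or KO replicate 3 (adjusted p = 0.121, 0.0805 and 0.0838). Both were lost with no filter on low counts (adjusted p = 0.059 and 0.0604). In all 2906 genes were called, 1501 higher and 1405 lower, with 416 at least 2-fold higher and 505 lower. Among genes of at least 10 CPM these were 168 and 173. The higher share went from 51.7% to 47.9% with DESeq2 size factors.

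**Figure D3:**
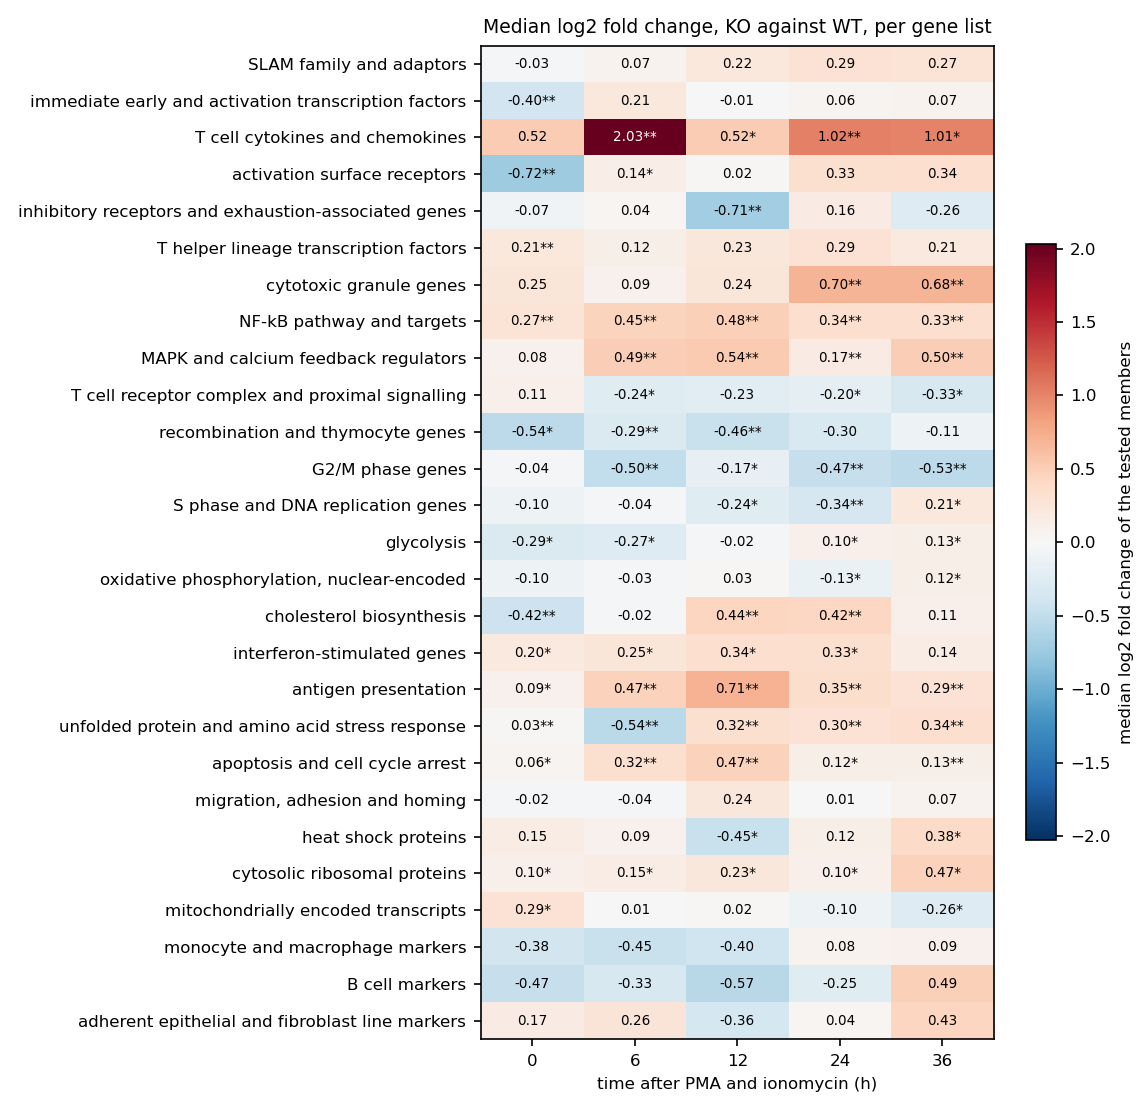
Median log2 difference of KO from WT (colour) for each gene list (vertical axis) at each time in hours (horizontal axis), with * where camera called the list and ** where the call also held with an estimated correlation. Cholesterol biosynthesis went from a median of -0.42 at 0 h to 0.44 at 12 h, and the unfolded protein list from -0.54 at 6 h to 0.32 at 12 h.

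Averaged over the 5 times, and among genes of at least 10 CPM called the same way at 4 or more times without overlap between libraries, the largest rises in KO were in SLAMF7 (log2 3.59, SE 0.133, adjusted p = 1.13e-17), PLAU (2.89), XIRP1 (2.83), the interferon-induced GTPase GBP4 (2.37), CYTIP (2.36) and FAM110B (2.33). Next came GZMB (2.30), TXNIP (2.25), the complement regulator CD55 (2.15) and the non-coding RNA ST3GAL6-AS1 (2.10). The largest falls were in RNF212 (adjusted p = 1.24e-24), CPXM1 (-6.17), IGLL1, a surrogate light chain gene (-5.26), and CD40LG (-4.95). Next came ZBTB16, the transcription factor PLZF, PREX2 (-3.52), ADD2 (-3.49), CLCA1, TOX2 (-3.23) and ALDH1A2, a retinoic acid synthase (-3.16). RNF212, ZBTB16 and CLCA1 had 3 or fewer counts in a KO group, so no average fold is given. ZBTB16 rose in WT from 1.84 ± 0.922 to 224 ± 12.6 CPM over 36 h, and in KO from 0.0283 CPM to 23.1 ± 5.19 CPM. In all, 146 genes were called in the same direction at all 5 times, 52 higher and 94 lower. The average called 6557 genes, 3268 higher and 3289 lower, with 241 at least 2-fold higher and 1086 lower, and 240 and 601 without the 12 h libraries. Among genes of at least 10 CPM these were 101 and 112 with all times, and 91 and 110 without the 12 h libraries. The higher share went from 49.8% to 41.6% with DESeq2 size factors. Fold changes between genotypes correlated across genes between times with r from 0.109 (0 h with 36 h) to 0.452 (0 h with 12 h). With no filter on low counts these r were 0.0181 and 0.223, and without 1 library they ran from 0.0385 to 0.114 and from 0.241 to 0.452.

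Lists in the average showed G2/M genes lower in 24 of 25 cases (24 adjusted over the list alone; median log2 -0.31, adjusted p = 6.13e-15). Antigen presentation genes were higher in 13 of 18 cases and lower in 3, NF-kB genes in 11 of 19 and 1 (14 and 1 adjusted over the list alone), apoptosis and arrest genes in 12 of 24 and 4, and MAPK and calcium feedback genes in 11 of 22 and 2 (13 and 2 adjusted over the list alone). Cytokines were higher in 8 of 25 cases and lower in 2 (9 and 2 adjusted over the list alone; median log2 1.10), T helper factors in 12 of 24 and 4, and cytotoxic granule genes in 7 of 14 and 1 (8 and 2 adjusted over the list alone). The unfolded protein list (8 of 25 higher, 10 lower; adjusted p = 0.812) and activation receptors (5 of 18 higher, 5 lower; adjusted p = 0.549) were not called. Thymocyte genes were lower in 8 of 18 cases and higher in 2. Calls that ended with an estimated correlation were ribosomal proteins, 35 of 45 higher (adjusted p = 0.294 with an estimated correlation), interferon-stimulated genes, 15 of 31 higher and 2 lower (adjusted p = 0.242). The same held for the T cell receptor list, 12 of 23 lower and 6 higher (adjusted p = 0.32), S phase, 12 of 25 lower and 1 higher (adjusted p = 0.32), and cholesterol, 9 of 24 higher and 2 lower (adjusted p = 0.443), with a median of 0.11 and a mean of -0.10. The SLAM family (7 of 14 higher, 4 lower; adjusted p = 0.272), migration genes (9 of 24 higher, 7 lower; adjusted p = 0.851), oxidative phosphorylation (1 of 34 higher; adjusted p = 0.83), glycolysis (6 of 22 higher, 7 lower; adjusted p = 0.693) and heat shock proteins (6 of 13 higher, 5 lower; adjusted p = 0.693) were not called. Markers of monocytes (1 of 8 higher, 4 lower; adjusted p = 0.371), B cells (1 of 8 higher, 1 lower; adjusted p = 0.851) and adherent lines (1 of 7 higher; adjusted p = 0.825) were not called. Of the erythroid list only ITGA2B could be tested as a gene. CD69 was lower (log2 -0.44, adjusted p = 0.000368). Its difference was by far the largest at 0 h and was not called at 6 or 12 h, so the average does not describe the whole time course. SLAMF6 was higher (log2 0.22, adjusted p = 0.0043, and 0.101 without the 36 h libraries). TBX21 was higher (log2 1.17, adjusted p = 0.0239). That call was lost without KO 0 h replicate 3 (0.43), without the 36 h libraries (0.0635) and with no filter (0.0775). IL2 (adjusted p = 0.0611) and IFNG (adjusted p = 0.15) did not pass. Both passed with DESeq2 (adjusted p = 3.26e-08 and 4.79e-06) and with the replicate block (0.0381 and 0.0245). IL2 also passed without WT 24 h replicate 3 (0.0465), KO 6 h replicate 2 (0.0331) or KO 12 h replicate 1, 2 or 3 (0.0413, 0.0436 and 0.0498).

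The last question was whether activation changed genes differently in the 2 genotypes. At 0 h the titles carry A in WT and B in KO, and at 36 h C in both. In changes to 36 h and in the joint test, an effect of the letters cannot be told from one of genotype. The 10 genes with the smallest joint p included ANXA1, ADAM19 and genes of the endoplasmic reticulum stress response. HSPA5 fell in WT from 2247 CPM at 0 h to 633 ± 88.9 CPM at 36 h and rose in KO from 676 to 998 CPM, a difference in log2 change of 2.39 (SE 0.151, adjusted p = 5.93e-14). HERPUD1, SDF2L1, MANF, HSP90B1 and DDIT3 also differed, with HERPUD1 at 2.57 (SE 0.145) at 12 h and DDIT3 at 2.22 (SE 0.182) at 36 h. ANXA1 fell in WT from 184 to 28.97 CPM over 36 h and was at 200 and 197 CPM in KO (difference 2.64, SE 0.151, adjusted p = 4.28e-15). ADAM19, a cell surface protease, reached 43.8 CPM in WT and 353 CPM in KO at 36 h (difference 3.23, adjusted p = 4.37e-11). The chaperone HSP90AA1 differed by -0.99 at 12 h. WT levels of HSPA5 and HERPUD1 were above those of KO at 0 h, the time against which these changes are measured. SLAMF6 differed in its change to 24 h by 0.77 (adjusted p = 0.015; 0.0627 without WT replicate 1 of 24 h and 0.0616 without KO replicate 3 of 24 h).

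**Figure D4:**
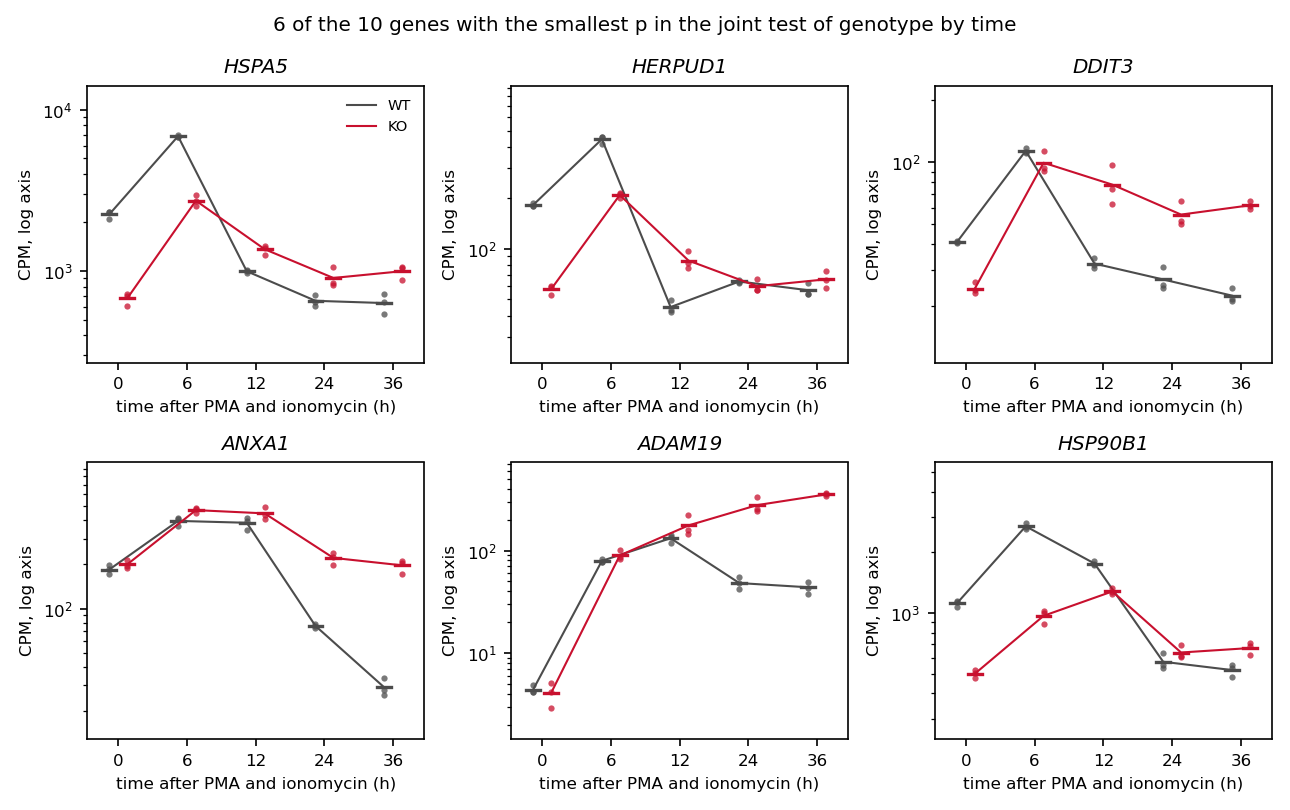
Levels of HSPA5, HERPUD1, DDIT3, ANXA1, ADAM19 and HSP90B1, 6 of the 10 genes with the smallest joint p, in CPM (log scale) against time in hours (steps not to scale), with points for libraries and short bars and lines for means of 3 libraries. HSPA5 in WT lay above KO at 0 and 6 h and below it from 12 h on.

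By list, cholesterol genes changed more upward in KO than in WT in 8, 18, 17 and 14 of 24 cases at 6, 12, 24 and 36 h with 0 downward (11, 19, 22 and 18 adjusted over the list alone), with medians of 0.42, 0.87, 0.96 and 0.63. Unfolded protein genes did so in 10, 8 and 9 of 25 cases at 12, 24 and 36 h with 0 downward (10, 11 and 12 upward adjusted over the list alone), with medians of 0.26, 0.22 and 0.43. Activation receptors did so in 3, 2, 6 and 7 of 18 cases with 0, 0, 1 and 1 downward (10, 7, 8 and 9 upward adjusted over the list alone), among them CD69 by 1.48 at 6 h (adjusted p = 0.00473). These receptors started lower in KO, with a median of -0.72 against WT at 0 h and of 0.14, 0.02, 0.33 and 0.34 later, when no difference was called with an estimated correlation. CD69 itself was at 662 against 675 CPM at 6 h. Glycolysis genes did so in 10 of 22 cases at 24 h (12 adjusted over the list alone; adjusted p = 0.0421 with an estimated correlation), and the calls at 12 h and 36 h, with 8 and 11 genes, had an adjusted p = 0.057 with an estimated correlation. G2/M genes changed more downward in 4, 6 and 9 of 25 cases at 6, 24 and 36 h (adjusted p = 0.0893, 0.121 and 0.121 with an estimated correlation). No difference in change was called for IL2, IFNG or TBX21 (joint adjusted p = 0.758, 0.888 and 0.208). IL2 and IFNG had few counts at 0 h. Their differences in the change to 6 h had SEs of 4.69 and 5.468 in log2, and that of TBX21 had 1.395. The lack of a call therefore does not exclude large differences. TBX21 passed the joint test without KO 6 h replicate 2 (0.0162) or KO 12 h replicate 1 (0.0495) and with DESeq2 (0.0488). Without both of these libraries IL2 and TBX21 passed it (0.0421 and 0.000169). In all 666, 440, 794 and 2013 genes differed at 6, 12, 24 and 36 h, and 2109 in the joint test. The last 2 of these counts cross the title letters. At 12 h the change from 0 h was more upward in KO in 68.9% of these genes, and in 56.9% with DESeq2. With DESeq2 the counts rose to 1062, 710 and 1245 at 6, 12 and 24 h and 3180 in the joint test. With the replicate block they rose to 1122, 691, 1285 and 3183. The counts fell to 405, 443, 411 or 381 at 6 h without WT 0 h replicate 1, WT 6 h replicate 1, WT 6 h replicate 3 or KO 0 h replicate 1, and to 1314 or 1324 at 36 h without WT 0 h replicate 1 or KO 36 h replicate 3. At 24 h they fell to 473, 526, 513, 470, 474 or 441 without WT 0 h replicate 1, WT 24 h replicate 1, WT 24 h replicate 2, KO 0 h replicate 1, KO 0 h replicate 3 or KO 24 h replicate 3.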

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

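Among the tests of this part, those of a mislabelled time, a weaker calcium arm, a difference in depth at 12 h, the average without the 12 h libraries and a copy number difference of equal size at every time were chosen after the results were seen. Genes and lists whose change from 0 h differed between KO and WT were singled out by a test of the difference itself. Other splits of the libraries, the spread of cytokine genes, the balance of 2-fold calls and the order along the chromosomes were examined for technical explanations.

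The count of such genes was 666 at 6 h, 440 at 12 h, 794 at 24 h and 2013 at 36 h, and 2109 in the joint test. Changes to 36 h and the joint test cross the title letters, whose effect cannot be told from genotype there. Changes were measured from 0 h, where activation receptors, cholesterol and glycolysis genes had medians of -0.72, -0.42 and -0.29 in KO against WT. In log2 units ANXA1 differed by 2.64 at 36 h, HSPA5 by 2.39 at 36 h, HERPUD1 by 2.57 at 12 h, ADAM19 by 3.23 at 36 h and HSP90B1 by 1.52 at 36 h. SDF2L1 differed by 1.79 at 12 h, MANF by 1.73 at 36 h, DDIT3 by 2.22 at 36 h and HSP90AA1 by -0.99 at 12 h. PDGFC differed by 2.52 at 24 h, SLAMF6 by 0.77 at 24 h and CD69 by 1.48 at 6 h. Cholesterol biosynthesis had median differences of 0.42, 0.87, 0.96 and 0.63 at 6, 12, 24 and 36 h, activation receptors of 1.16, 0.95, 1.02 and 1.03, and MAPK and calcium feedback genes of 0.46, 0.36, 0.41 and 0.77. The unfolded protein list had medians of 0.26, 0.22 and 0.43 at 12, 24 and 36 h, and cytotoxic granule genes of 0.63 and 0.55 at 24 and 36 h. Immediate early factors had a median of 0.68 at 6 h, T helper factors of -0.41 at 12 h and glycolysis of 0.55 at 24 h.

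Exchanging the genotype labels within times in 60 groupings gave as many calls in 1 grouping, the real one, for the average (6557 calls, highest other 841), for 6 h (666, highest other 253), for 36 h (2013, highest other 1168) and for the joint test (2109, highest other 1095). For 12 h and 24 h, 2 groupings did, and the highest other gave 1988 calls against 440 and 1218 against 794, in groupings that exchanged all genotype labels at 1 of the compared times and none at the other. Such a grouping adds the genotype differences of both times, so genotype is a structure it still follows. For gene lists in the average 2 groupings did, with 14 real and 15 in the highest other. The median of the other groupings was 5 lists, and a grouping with 0 genes called in the average had 13. Camera with the preset correlation therefore called lists under exchanged labels too, and a list call with it alone is weak. Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05, and in each comparison 1 split, the real one, reached its count while the highest other called 0 genes. The real counts were 6004, 7051, 6468 and 8669 in WT and 5319, 5470, 6634 and 7956 in KO at 6, 12, 24 and 36 h. For KO against WT they were 1679, 2288, 2304, 986 and 3981 at 0, 6, 12, 24 and 36 h. Every other grouping or split mixed libraries of both kinds within some group. That puts the real difference into the spread and lowers the calls. For the differences in change and the joint test, these counts therefore do not show what chance alone would give. Exchanged labels also cannot tell genotype from the title letters at 0 to 24 h.

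Cytokine genes spread widely among KO libraries at 6 and 12 h, where KO 6 h replicate 2 held IL2 at 26.9 CPM against 108 and 104 CPM and KO 12 h replicate 1 at 49.9 CPM against 10.7 and 12.6 CPM. A swap of 6 h and 12 h labels was excluded with a time score over 222 genes that separate these times in WT. WT libraries scored about -1 at 6 h and about 1 at 12 h. The highest score of the KO 6 h libraries was -1.09. The KO 12 h libraries scored 0.188 to 0.295, short of WT at that time. Other errors of time were not tested, since the score was not built for 0, 24 or 36 h. A mislabelled genotype was excluded, since the lowest genotype score of these KO libraries was 0.907 over 131 genes and the highest of the WT libraries 0.0862. Calcium-dependent genes lay below phorbol ester-driven genes in the libraries low in IL2, by a log2 of -1.26 at 6 h and -1.92 at 12 h, but that list holds IL2 and other cytokine genes of the pattern, so this decides nothing. The cause stays open.

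More genes were at least 2-fold lower than higher in KO at 12 h, 868 against 298, and in the average, 1086 against 241. At 24 h this was not so, with 320 lower and 335 higher. A difference in depth was excluded as the whole cause at 12 h, since with the 12 h libraries thinned to 13.8 M counts the lowest ratio of lower to higher genes in 5 thinnings was 2.58. Extra low-level reads in the WT libraries of 12 h could account for the balance at that time, because the ratio of lower to higher genes was 0.559 among genes of at least 10 CPM. The other times leaned the same way. At 0, 6, 24 and 36 h the ratio was 13, 3.05, 1.95 and 1.76 under 1 CPM. It was 1.08, 0.641, 0.61 and 1.03 at 10 CPM or more. The 12 h libraries alone did not make the balance of the average, where without them 601 genes were lower and 240 higher, a ratio of 2.5, against 1086 lower genes with them. In the average without them the ratio was 3.78 under 1 CPM and 1.21 at 10 CPM or more, so the remaining balance also lay in low-level genes. The source of the low-level reads stays open, and no biological explanation was tested.

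Along the chromosomes 1 of 1138 windows of 50 genes passed the threshold of 0.2 with the same sign at 5 times. It lies on chromosome 8 at 143289676 to 144853736 (GENCODE 29 on GRCh38), with a median of 0.221 in the average against 0.22 for the largest of 1000 shuffles, and 23 genes higher and 0 lower. Its medians were 0.323, 0.213, 0.268, 0.027 and 0.114 at 0, 6, 12, 24 and 36 h. A copy number difference would be of about equal size at every time. The changes in median of -0.19 from 0 h to 24 h and -0.229 to 36 h were as far from the centre in 3.87% and 3.34% of windows, which over 4 times compared neither excludes nor supports this. It holds 23 of the 5094 called coding genes with a place, so it leaves the rest unaddressed. A copy number difference and a regional effect without one both stay open, since no DNA was measured.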

How the results depend on the processing

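Fits without both replicate 3 libraries of 24 h, without the outlying KO libraries and without the 12 h libraries were chosen after seeing the data. No named gene reversed. Single lists were followed only with DESeq2 size factors and with an estimated correlation, and no called list reversed there. With DESeq2 size factors no count of calls moved by more than 1.5-fold. The share of calls higher in KO did fall under 50% with these factors, to 49.2%, 38.8%, 46.0% and 47.9% at 6, 12, 24 and 36 h, and the more frequent direction also changed in WT at 6 and 12 h and in KO at 24 h. With DESeq2 the difference in the change from 0 h gave 1062, 710 and 1245 genes at 6, 12 and 24 h and 3180 in the joint test, and with the replicate block 1122, 691, 1285 and 3183. The joint test gave 1011 without the 36 h libraries. Without the 12 h libraries, which also leaves fewer times to test, its count did not move by more than 1.5-fold. The 12 h difference gave 682 without the outlying KO libraries. KO against WT at 24 h gave 1259 without both replicate 3 libraries and 986 with the 6 libraries alone. Camera called 299 pairs of list and comparison, 190 of them with an estimated correlation. Why these counts moved was not tested. Correlations of fold changes moved in 14 of 14 cases with no filter and in 86 cases when 1 library was left out.

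Leaving out 1 library at a time gave 3708 to 4051, 5181 to 5807, 6388 to 7016 and 7252 to 7623 genes for WT at 6, 12, 24 and 36 h, and 4837 to 5383, 4867 to 5350, 5924 to 6421 and 6811 to 7212 for KO. For KO against WT it gave 650 to 1123, 1363 to 1911, 1353 to 2068, 1354 to 1905 and 1978 to 2299 at 0, 6, 12, 24 and 36 h and 6028 to 6844 in the average. For the difference in the change it gave 381 to 669, 298 to 545, 441 to 1133 and 1314 to 1871, for the joint test 1618 to 2657, and for lists 286 to 311. Among values of named genes, leaving out a library kept the call in 13884 cases and ended it in 438, and of values not called it left 404 so and made 10 calls. The fit of 6 libraries alone ended 43 and made 1, no filter ended 23, DESeq2 ended 6 and made 7, and the replicate block ended 1 and made 4. DESeq2 size factors ended 7. Without the 36 h libraries 34 calls ended and 189 values were left as they were. Without both replicate 3 libraries of 24 h 19 ended, without the outlying KO libraries 13 ended and 5 were made, and without the 12 h libraries 5 ended. A fit of the table of the whole series was not run, because its values are the same. Depth limits the genes near 0 counts, such as IL2 and IFNG at 0 h.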

Other observations

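LEF1 and CXCR4 were chosen after their values were seen. LEF1, a transcription factor of immature T cells, was at 277 ± 20.5 CPM in WT and 277 ± 36.5 CPM in KO at 0 h. At 36 h it was at 1075 ± 58.1 CPM in WT and 302 ± 10.8 CPM in KO, and its change from 0 h differed between genotypes (adjusted p = 3.34e-09). CXCR4, the receptor for the chemokine CXCL12, fell over 36 h from 463 ± 27.7 to 272 ± 20.6 CPM in WT and from 578 ± 57.3 to 78.1 ± 6.14 CPM in KO, and these changes differed too (adjusted p = 1.71e-10). Changes to 36 h in both genes cross the title letters.

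The summed level of olfactory receptor genes, looked at after seeing the data, was 97.8 ± 34.7 CPM in the WT libraries of 12 h and 24.6 ± 1.04 CPM in the KO libraries of 12 h. In WT it was 31.3 ± 13, 27.9 ± 6.11, 33.5 ± 6.63 and 22.6 ± 4.02 CPM at 0, 6, 24 and 36 h. In KO it was 14.9 ± 2.81, 19.6 ± 3.5, 21.4 ± 2.47 and 18.2 ± 1.58 CPM.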
